A study of Populus ussuriensis with 12 samples.

How the data were processed

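RNA-seq was carried out on roots of Populus ussuriensis, a poplar species propagated clonally in vitro, from wild-type plants and from plants overexpressing PuHox52. Plants of each genotype had been kept for 3 weeks on medium with normal nitrogen (N) or on low-N medium, which gave 4 groups of 3 libraries. The series' design text calls the 3 libraries of a group biological replicates.

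The deposited values are FPKM (fragments of a gene scaled to gene length and to the mapped fragments of the library) in 1 table of 34699 gene IDs by 12 libraries, with 1 column per library and no pooling. The submitters' processing notes name TopHat and DESeq2 without a version or a role. The genome build, the gene annotation and the program that turned alignments into FPKM are not given in the sources used here. Per the labels' protocols, RNA was extracted with CTAB and libraries were made by a standard Illumina protocol at 2 sequencing companies, without a statement of which company handled which library. Columns were assigned to samples by the short column label that GEO's description field gives for each sample, and 0 other per-sample columns were present. The table does not pair its Potri IDs with gene names or descriptions and no annotation was used here, so genes are given by ID. Gene lists that had been fixed by name and function could not be run for the same reason. The row of the overexpressed gene is likewise not named in the table.

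FPKM carries no counts, but its low values moved in steps. For each library, the most frequent ratio to wild type, normal N, replicate 1, among genes below 0.15 FPKM in all libraries, was taken as the ratio of what 1 fragment is worth. With these ratios, 100% of the values of 976 low genes detected in at least 3 libraries lay within 0.1 of a whole number of fragments, taking the smallest value of a gene as 1, 2 or 3 fragments, against 52.3% when equal depths were assumed. Relative depth ran from 1 to 1.22 in the normal-N libraries and from 0.447 to 0.501 in the low-N libraries, a 2.27-fold difference of the means. Absolute depth is unknown, so no counting intervals are given, and values of weakly expressed genes are less precise at low N.

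Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept (24570 genes). Values were taken to log2(FPKM + 1) and fitted in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with a mean-variance trend and robust estimation) in a model with 1 mean per group over all 12 libraries, which left 8 residual degrees of freedom. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Each gene was tested for overexpression against wild type at normal N and at low N, for low N against normal N in each genotype, and for the interaction, which is the genotype effect at low N minus that at normal N. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes are called changed. A count model was not used because FPKM values are not counts. On data simulated for the normal-N genotype comparison over 24570 genes, with 200 genes changed, the procedure called 46.3% of genes changed by 0.5 on the log2 scale, 91.0% of those changed by 1 and 98.5% of those changed by 2, with 7 false calls and 0 sign errors.

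The IDs named were set by the part of a rule that covers data without gene names: in each pairwise comparison the 2 risen and the 2 fallen IDs with the largest change among those called, with groups that did not overlap and at least 5 FPKM in the higher group, plus the 1 ID with the largest smaller overexpression effect of both N supplies. The rule, the design, the gene lists and the other settings were set before the data were examined. These settings were a pseudocount of 0.1, no filter and a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, library weights, a fit without trend and robust estimation, a fit on the 2 groups alone, a fold threshold, a replicate block and leaving out each library in turn.

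Fold changes were correlated across genes, which are not independent replicates, for 4 pairs of comparisons. The pair of the genotype effect at low N and the wild-type response to low N was added after seeing the data. Errors of these correlations are jackknife standard errors over libraries. Where 2 comparisons shared the 3 wild-type libraries of one N supply, 100 data sets with unchanged groups were simulated from the genes' residual spread, and the simulated correlation and covariance are given beside the observed ones. Library replicates within groups correlated at 0.976 to 0.996 (Pearson, log2 values), and at most 0.615% of the tested genes had identical values in any pair of libraries.

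For the order of genes by ID, genes with a mean of at least 5 FPKM in every group were grouped by the number inside the ID in bins of 10000, and bins with at least 20 such genes were kept. Each library's log2 FPKM was set relative to the mean of the 6 libraries of the same N supply and centred on the other genes. The end of the run of Potri.013G IDs that stood apart was placed with a single change point in the normal-N libraries. This step was added after seeing the data.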

Results

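The data compare roots of wild-type Populus ussuriensis and of plants overexpressing PuHox52, grown for 3 weeks at normal or low N, with 3 libraries in each of the 4 groups. At least 1 FPKM was reached by 22913 ± 53 genes in wild type at normal N, by 22144 ± 38 in overexpression plants at normal N, by 23588 ± 67 in wild type at low N and by 23305 ± 156 in overexpression plants at low N (mean ± SD, n = 3). The low-N libraries had a lower depth as inferred from the steps of low FPKM values. It was 0.447 to 0.501 against 1 to 1.22 for the normal-N libraries, relative to wild type, normal N, replicate 1. The median SD of a gene within a group, on the log2 scale, was 0.0974 and 0.0768 in wild type and overexpression plants at normal N, and 0.108 and 0.129 at low N.

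The N supply separated the libraries along the first principal component, which held 66% of the variance. The second component held 18.1% and parted the genotypes at low N, while the genotypes at normal N lay close together on it. The third component held 7.13% and parted the genotypes at normal N, with wild type at 28.5 to 30 and overexpression at -29.4 to -26.3.

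**Figure D1:**
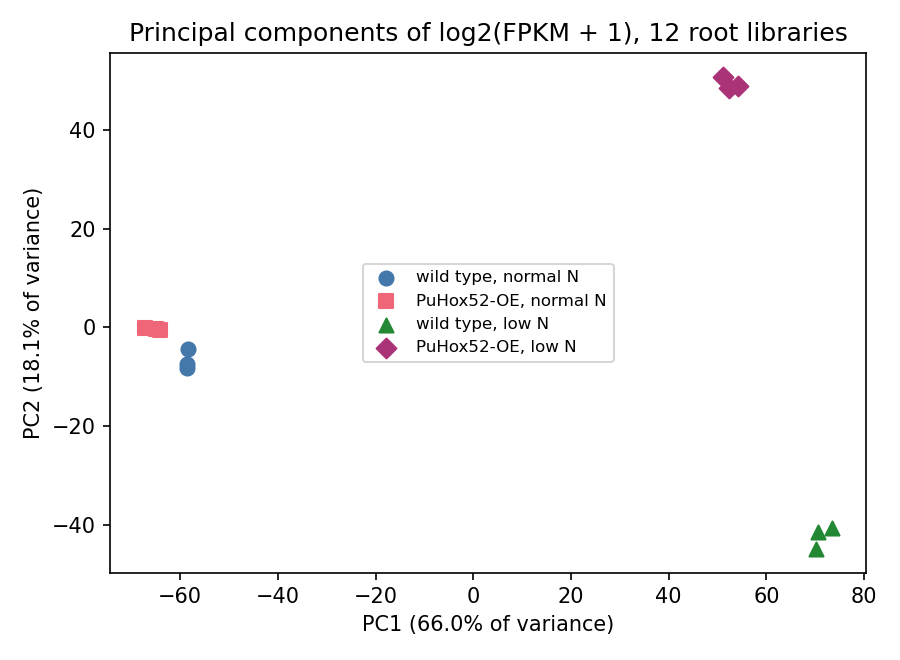
Principal components of log2(FPKM + 1) over 24570 genes, with each point 1 of the 12 libraries, coloured by group. The first component (66%) parts normal N from low N and the second (18.1%) parts wild type from PuHox52 overexpression at low N.

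The first question was which genes differ between PuHox52 overexpression and wild type at normal N. Potri.014G103000 stood far above all other IDs: it rose from 7.39 ± 0.719 FPKM in wild type to 2305 ± 75.6 in overexpression roots (SD, n = 3), a 312-fold higher mean. Its log2 fold change was 8.11 ± 0.279 (SE; limma, Benjamini-Hochberg adjusted p = 3.07e-07). The next risen ID by the naming rule, Potri.002G022600, went from 9.41 ± 1.08 to 62.1 ± 4.12 FPKM. Potri.018G047300 fell from 73.0 ± 2.75 to 1.33 ± 0.148 FPKM, a 55.0-fold lower mean, and Potri.014G066300 fell from 69.1 ± 4.08 to 4.80 ± 1.02 FPKM.

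In all, 5851 of 24570 genes (23.8%) were called at normal N by limma at an adjusted p under 0.05, 1607 higher and 4244 lower in overexpression roots. Most of these changes were small, with a median size of 0.45 on the log2 scale. Only 59 of the higher and 476 of the lower genes changed by at least 1 on that scale. The median of all tested genes was -0.08, and the split by direction followed the scaling: 27.5% of calls were higher with the deposited values, 58.4% after median-of-ratios scaling and 52.2% after quantile normalization. The count itself was 3706 without overexpression replicate 3 and 11246 with library weights.

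At low N, 11757 genes (47.9%) differed between the genotypes, 4322 higher and 7435 lower in overexpression roots. A change of at least 1 on the log2 scale was found for 1044 higher and 892 lower genes. Potri.016G057600 showed the largest rise, from 46.9 ± 29.5 FPKM in wild type to 2782 ± 777 in overexpression roots (SD, n = 3; log2 fold change 5.99 ± 0.345 SE, limma adjusted p = 3.98e-07). At normal N the same ID lay at 3.44 ± 0.0391 and 6.56 ± 0.667 FPKM, which did not pass the test (limma adjusted p = 0.14). The normal-N libraries did not overlap, at 3.40 to 3.48 FPKM in wild type and 5.79 to 6.95 in overexpression roots. The test uses a spread shared by all groups, which includes the wide low-N values of this ID. Potri.014G103000 rose from 44.9 ± 14.6 to 1653 ± 615 FPKM, a 36.8-fold higher mean. Among the fallen genes, Potri.001G305400 went from 21.5 ± 3.03 to 0.17 ± 0.191 FPKM, and Potri.014G022900 from 454.6 ± 35.3 to 31.2 ± 19.1 FPKM. The share of higher calls was 36.8% with the deposited values, 51.6% after median-of-ratios scaling and 44.7% after quantile normalization. That low N held more calls than normal N depended on the fit. Library weights gave 10669 calls at low N and 11246 at normal N. Fits on the 2 groups alone gave 9608 and 8535.

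**Figure D2:**
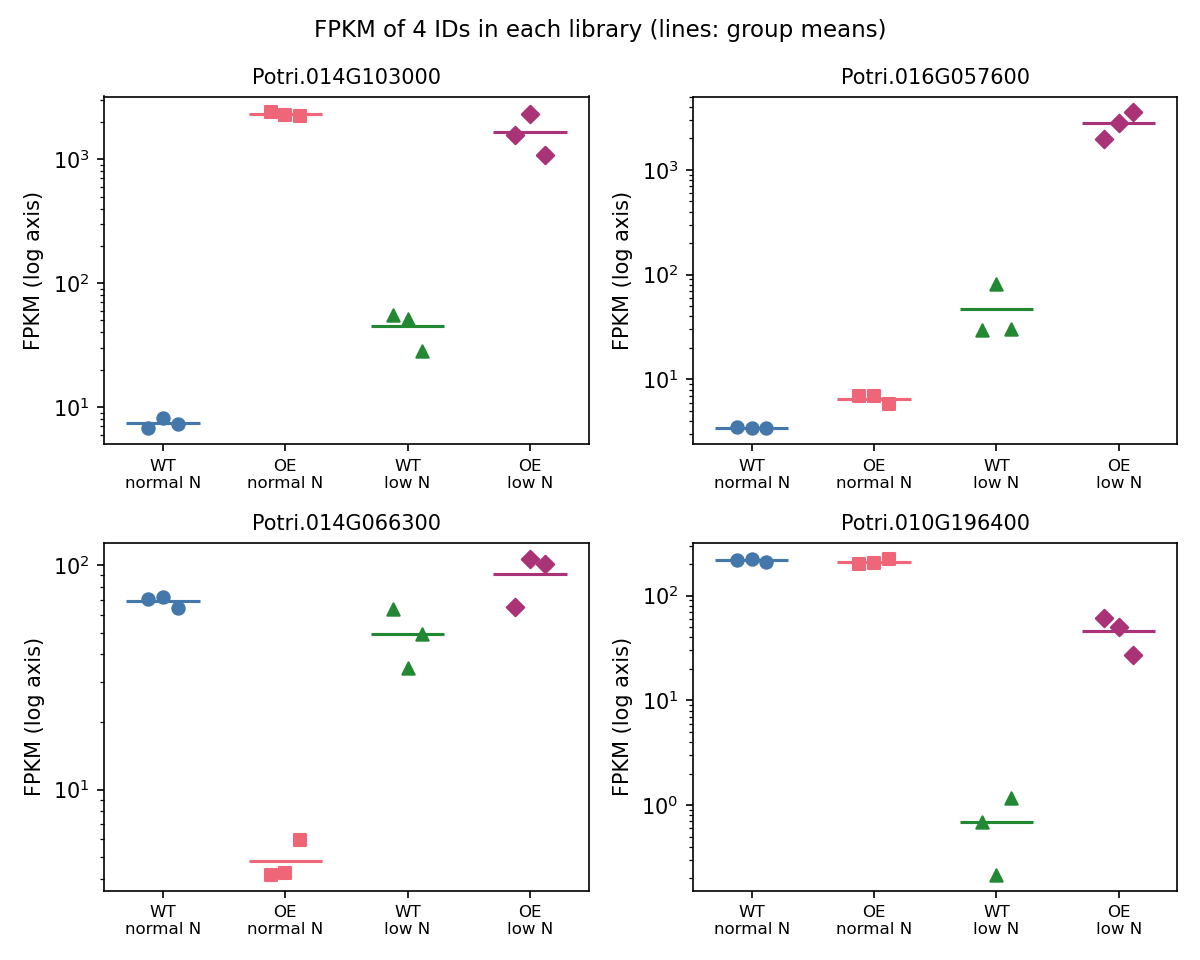
FPKM on a log axis of Potri.014G103000, Potri.016G057600, Potri.014G066300 and Potri.010G196400 in each library, with lines at the group means (n = 3). Potri.014G103000 is high in all overexpression libraries at either N supply, and Potri.016G057600 is high in the overexpression libraries at low N alone, with a mean of 2782 FPKM.

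The effects of overexpression at the 2 N supplies were then set against each other, which involves no shared library. Across genes, their log2 fold changes correlated at r = 0.06 with a jackknife SE of 0.0433, which is within 2 SE of 0. Of the 1607 genes higher at normal N, 542 were also higher at low N, against 283 for independent lists, and 557 were lower, against 486. Of the 4244 genes lower at normal N, 1547 were also lower at low N, against 1284 for independent lists, and 657 were higher, against 747. These overlaps used the deposited scaling and were not counted under the other scalings, which moved the split by direction. Potri.014G103000 was the 1 ID raised by at least 2 on the log2 scale at both N supplies. The smaller of both effects reached 1.95 for the next ID.

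The interaction, which asks whether the genotype effect differs between N supplies, was called for 8832 genes (35.9%), 4612 with a more positive effect at low N and 4220 with a more negative one (limma, adjusted p under 0.05). The larger side turned over with the scaling, at 4393 and 4480 after median-of-ratios scaling and 4125 and 4963 after quantile normalization. Potri.014G066300 was an example of a reversed effect. It was lower in overexpression roots at normal N and higher at low N, at 49.5 ± 14.6 FPKM in wild type and 91.0 ± 22.5 in overexpression roots, with an interaction of 4.49 ± 0.325 (SE) on the log2 scale. Potri.002G022600 turned the other way: it was higher in overexpression roots at normal N and lower at low N, with 37.9 ± 21.5 FPKM in wild type and 4.61 ± 1.70 in overexpression roots, and an interaction of -5.31 ± 0.46 (SE).

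**Figure D3:**
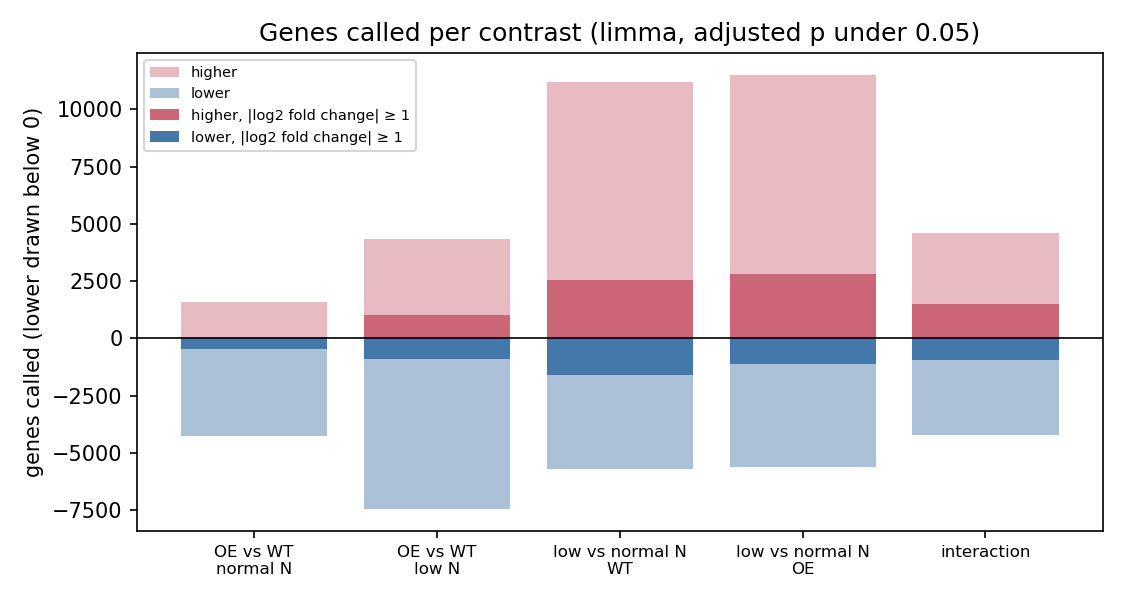
Number of genes called per contrast, with higher genes drawn above 0 and lower genes below 0, and the darker bars marking changes of at least 1 on the log2 scale. The low-N responses hold the most calls, 16909 in wild type and 17129 in overexpression roots, and the genotype effect at normal N the fewest of the pairwise contrasts, 5851. With library weights the genotype effect was called for 11246 genes at normal N and 10669 at low N, so their order depends on the fit.

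Many genes differed between low N and normal N in both genotypes. Since 2 sequencing companies are named without a link to libraries, N supply and library batch cannot be told apart for these calls. In wild type, 11209 genes rose and 5700 fell, together 68.8% of those tested, and 2542 and 1612 of them changed by at least 1 on the log2 scale. Potri.007G062282 was listed at 0 in all 3 wild-type libraries at normal N and reached 939, 856 and 802 FPKM at low N. Potri.007G062061 was listed at 0, 0 and 0.14 FPKM at normal N and reached 686.1 ± 161 at low N. Potri.010G196400 fell from 217.9 ± 9.33 to 0.69 ± 0.476 FPKM (log2 fold change -7.05 ± 0.268 SE, limma adjusted p = 4.64e-09), and Potri.005G172400 fell from 1370 ± 82.6 to 20.7 ± 12.1 FPKM. Potri.014G103000 also rose in wild type at low N, from 7.39 ± 0.719 to 44.9 ± 14.6 FPKM (log2 fold change 2.40 ± 0.279 SE, limma adjusted p = 2.47e-05).

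In overexpression roots, 11516 genes rose and 5613 fell at low N, together 69.7% of those tested, with 2795 and 1134 of them changed by at least 1 on the log2 scale. The 2 IDs with the largest rise were those of wild type: Potri.007G062282 was listed at 0 in all 3 libraries at normal N and reached 1108 ± 116 FPKM, and Potri.007G062061 was listed at 0, 0 and 0.0736 FPKM and reached 633.8 ± 77.2. Both IDs belong to a set of 38 genes, described below, with under 0.5 FPKM in every normal-N library. For that set, as for all calls between low N and normal N, N supply and library batch cannot be told apart. Potri.018G106000 went from 97.1 ± 3.84 FPKM to a listed 0 in all 3 low-N libraries, and Potri.005G193800 fell from 150.7 ± 4.46 to 2.27 ± 0.276 FPKM. Potri.014G103000 had 2305 ± 75.6 FPKM at normal N and 1653 ± 615 at low N in these plants, which did not pass the test (limma adjusted p = 0.105). It passed after median-of-ratios scaling, with a log2 fold change of -0.80, and without overexpression low-N replicate 2, with -0.82.

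The median of all tested genes moved by 0.19 in wild type and 0.22 in overexpression roots between the N supplies, and median-of-ratios scaling took it to 0.00 and 0.01. The split by direction moved with it: 66.3% of calls in wild type were rises with the deposited values, 49.6% after median-of-ratios scaling and 52.2% after quantile normalization. The corresponding shares in overexpression roots were 67.2%, 49.9% and 49.1%. The normal-N and low-N libraries also differed in inferred depth, by 2.27-fold.

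The low-N responses of the 2 genotypes, which share no library, correlated across genes at r = 0.68 (jackknife SE 0.017). Both set low-N against normal-N libraries, so a difference of depth or batch between the N supplies would enter both alike. The correlation and the overlaps below therefore cannot part N supply from such a difference. Of the 11209 genes that rose in wild type, 8515 also rose in overexpression roots, against 5254 for independent lists, and 3464 of the 5700 fallen genes also fell, against 1302. These overlaps were counted with the deposited scaling alone. Among the 6019 genes that changed by at least 1 on the log2 scale in either genotype, the interaction was called for 3577 (59.4%). The set held 2118 genes whose responses summed to below 0 over both genotypes, with a median log2 fold change of -1.32 in wild type and -1.03 in overexpression roots. The genes were selected anew under each scaling, so the sets differ. With sums below 0, the medians were -1.21 and -1.09 for 3026 genes after median-of-ratios scaling. They were -1.23 and -1.08 for 2966 genes after quantile normalization. For the 3901 genes with a sum above 0 the medians were 1.13 in wild type and 1.15 in overexpression roots with the deposited values. The order turned over with the scaling, at 1.15 and 1.14 for 2616 genes after median-of-ratios scaling and 1.18 and 1.11 for 2587 after quantile normalization. Of the genes with a sum below 0 and a called interaction, 716 had a smaller and 432 a larger response of the same direction in overexpression roots, and 406 had fitted responses of opposite direction. For sums above 0 the counts were 842, 807 and 373. Responses of opposite direction that were called in both genotypes were fewer, 198 for sums below 0 and 175 for sums above 0. The counts after scaling come from the newly selected sets and are not of the same genes. After median-of-ratios scaling the counts of smaller, larger and opposite responses were 925, 756 and 447 of 3026 genes with sums below 0. For the 2616 genes with sums above 0 they were 583, 525 and 327. After quantile normalization they were 922, 678 and 430 of 2966 genes, and 692, 443 and 356 of 2587 genes.

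**Figure D4:**
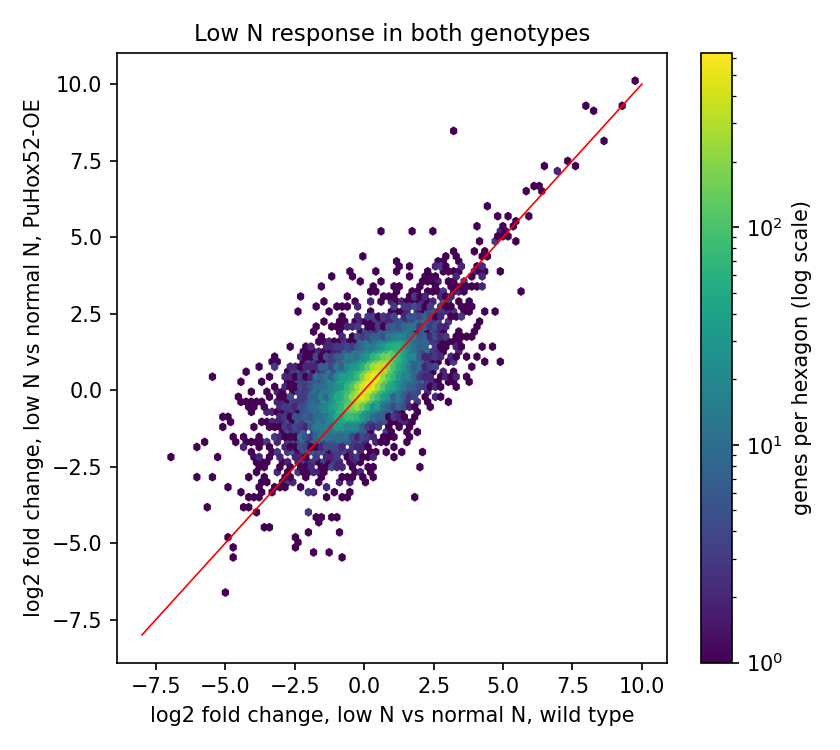
Log2 fold change of each gene between low and normal N in wild type (x axis) and in PuHox52 overexpression (y axis), as a density of genes on a log colour scale, with the line of equal response. The responses correlate at r = 0.68.

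Potri.010G196400 and Potri.005G172400 belong to the fallen genes with a smaller response in overexpression roots. In those plants Potri.010G196400 went from 210.1 ± 12.2 to 46.2 ± 17.3 FPKM and Potri.005G172400 from 1493 ± 5.44 to 419.5 ± 50.8 FPKM. Their interactions were 4.82 ± 0.378 and 4.28 ± 0.402 (SE) on the log2 scale. Potri.005G193800 is an example with a larger response: it went from 84.1 ± 6.96 to 50.8 ± 13.4 FPKM in wild type and from 150.7 ± 4.46 to 2.27 ± 0.276 FPKM in overexpression roots. Potri.010G196400 and Potri.005G172400 were named for their falls in wild type, and Potri.005G193800 for its fall in overexpression roots. That choice favours a smaller response in the other genotype.

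The genotype effect was finally set against the wild-type response to low N. At low N, 2158 of the 4322 genes higher in overexpression roots had fallen in wild type under low N, against 1003 for independent lists, and 4590 of the 7435 lower genes had risen, against 3392. The correlation across genes was -0.44. These comparisons share the 3 wild-type low-N libraries, and unchanged groups gave a simulated correlation of -0.502 with a covariance of -0.0108, against an observed covariance of -0.228. Unchanged groups gave 0 shared calls in 20 simulations, but they hold almost no calls by construction and are no baseline for these overlaps. Part of the excess over independent lists may come from the shared libraries. At normal N the correlation of the genotype effect with the wild-type low-N response was 0.15, with a covariance of 0.047 against a simulated 0.0107 (simulated correlation 0.499). Of the 1607 genes higher at normal N, 635 had risen in wild type at low N, against 733 for independent lists, and 645 had fallen, against 373. Of the 4244 lower genes 1350 had fallen, against 985, and 1788 had risen, against 1936. Here too the simulated mean of 0.05 shared calls is no baseline, and part of any excess may come from the 3 shared wild-type normal-N libraries. All overlaps with the wild-type response were counted with the deposited scaling alone.

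One run of IDs differed between libraries as a block. It ran from Potri.013G000100 to Potri.013G032200 and held 297 IDs, and the comparison used those with a mean of at least 5 FPKM in every group. At normal N these genes were 0.45 higher on the log2 scale in overexpression roots than the other 13681 genes (1.36-fold), and 94.2% of them lay above the median of the others. At low N they were 0.36 higher, but this rested on 1 wild-type library and was 0.13 without wild-type low-N replicate 2. That library lay 0.61 below replicate 1 and 0.71 below replicate 3 of its own group, with 100% of the compared genes lower in either case. Within each of the other groups, 2 libraries differed in the run by at most 0.0321, and wild-type low-N replicates 1 and 3 by 0.12. The run supplied 53 of the 1607 risen calls at normal N and 72 of the 4322 at low N. It held 214 of the tested genes (0.871%). Of these, 24.8% rose at normal N against 6.38% of the other tested genes, and 33.6% against 17.4% at low N. Calls in the other direction numbered 2 at normal N and 12 at low N.

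**Figure D5:**
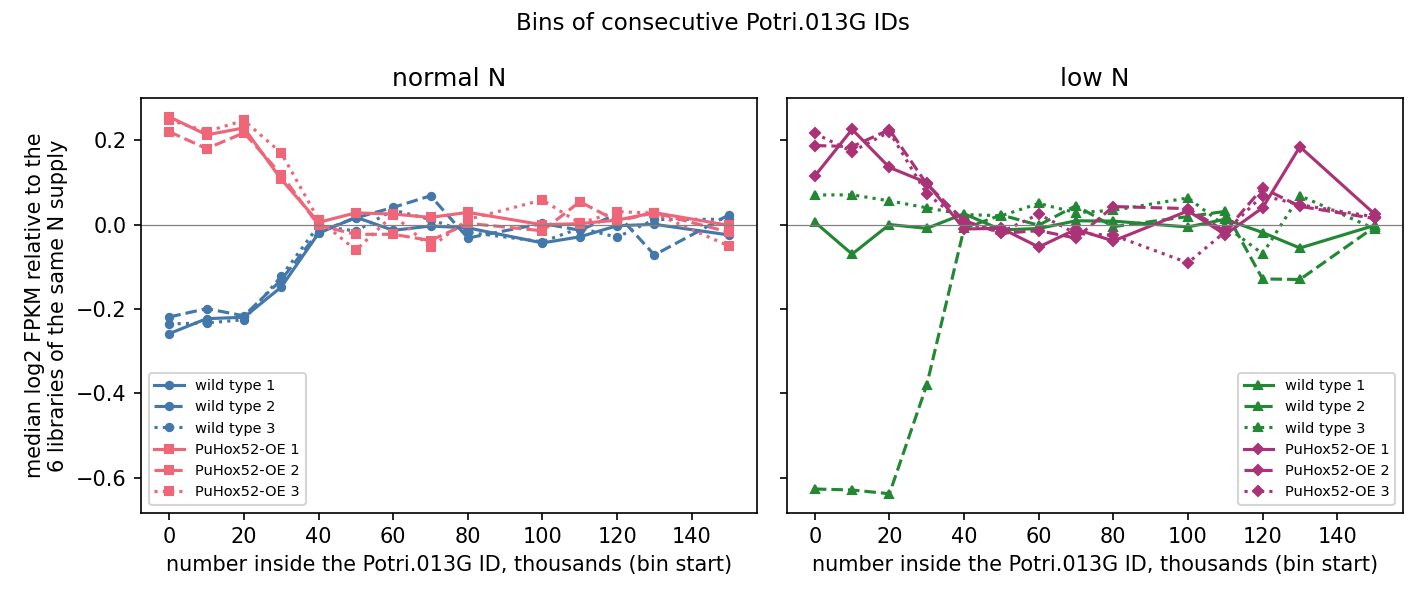
Median log2 FPKM of bins of consecutive Potri.013G IDs in each library, relative to the mean of the 6 libraries of the same N supply, against the number inside the ID. The first bins are higher in overexpression than in wild type at normal N by 0.45 on the log2 scale over the whole run, and wild-type low-N replicate 2 lies below the other libraries.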

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

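The tests of the run of Potri.013G IDs and of sequencing company, and the other settings for the interactions of named IDs, were chosen only after the result was seen. The genotype effect differed between the N supplies, by the interaction test, for 8832 genes. Of 100 drawn splits of the genotypes within each N supply, the real one included, 1 reached the real count, and the highest other gave 7024. The 14 other splits that left the low-N libraries parted by genotype gave 4933 to 7024 calls. Such splits carry the low-N genotype difference into the interaction, so high counts follow from their construction. The 85 that mixed the low-N libraries gave 270 to 704 calls where the normal-N libraries stayed parted by genotype. They gave 0 where the normal-N libraries were mixed too. The splits break the genotype effects along with the interaction, so whether chance can be excluded for the interaction is not settled by them, and the exchange of the genotypes at low N alone was not among those drawn. Among the named IDs the interaction on the log2 scale was -2.94 for Potri.014G103000, 5.81 for Potri.018G047300, 5.22 for Potri.016G057600, 4.82 for Potri.010G196400, 4.49 for Potri.014G066300, 4.28 for Potri.005G172400, -3.39 for Potri.001G305400, -3.44 for Potri.014G022900, -4.79 for Potri.005G193800 and -5.31 for Potri.002G022600, each with an adjusted p under 0.05 in limma. It was 0.353 for Potri.007G062282, which passed in limma but not after quantile normalization, with 0.02, nor without wild-type low-N replicate 3, with 0.30, or without overexpression low-N replicate 2, with 0.29. It was -1.59 for Potri.018G106000, which also passed, but both genotypes lay below 1 FPKM at low N, its size depends on the pseudocount, and it was -3.53 with a pseudocount of 0.1. It was -0.07 for Potri.007G062061, which did not pass (limma adjusted p = 0.816). The low-N values of Potri.018G047300 were also near the floor and overlapped, at 0.169 to 2.15 FPKM in wild type and 0.726 to 5.29 in overexpression roots. Its interaction mainly reflects the normal-N genotype effect of -4.99 on the log2 scale, and its size depends on the pseudocount. The named IDs were picked for large changes in pairwise comparisons, which favours large interactions among them.

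The pairwise comparisons have 10 splits each, too few for a share under 0.05. The real counts were 5851 and 11757 for the genotype effect at normal and low N, and 16909 and 17129 for the low-N response in wild type and overexpression roots. The real split alone (1 of 10) reached each of these counts, and the highest counts of the other splits were 1, 4, 0 and 0.

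The run of Potri.013G IDs is the pattern most open to a second look. A response to the overexpression alone is argued against by the wild-type low-N libraries, which differ from each other by up to 0.706 in the same run, more than the genotypes do at either N supply. Library scaling as an offset shared by all genes was removed by centring before the bins were formed, so the bins cannot test it. A shift spread over other bins of IDs is argued against at normal N, where none was raised by more than 0.109. None was raised at both N supplies by more than 0.0844. At low N alone other bins moved more, with 0.268 for the first bin of Potri.017G IDs. A candidate explanation is a different dosage of a stretch of the genome between plants of either genotype: 100% of its compared genes moved the same way between the wild-type libraries that differed most, and the run ended at Potri.013G032500 there and at Potri.013G032200 between the genotypes. It stays a hypothesis, since that the IDs are numbered along a chromosome is assumed, the log2 shift of 0.45 at normal N is below the 0.585 of 3 copies against 2 while wild-type low-N replicate 2 lay 0.61 below replicate 1 and 0.71 below replicate 3, and no DNA data were used.

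For the size of the low-N response, lower depth of the low-N libraries as the whole cause is argued against by well-expressed genes: 60.9% of the 6527 genes with a mean of at least 20 FPKM were called in both genotypes. These calls had no fold threshold and no required direction. They used the deposited scaling, with medians of 0.19 and 0.22, so they do not speak to an offset between the N supplies. A sequencing company or library batch that follows the N supply cannot be told apart from the N supply itself, because 2 companies are named without a link to libraries. The data hold a feature that goes with either: 38 genes lay under 0.5 FPKM in all 6 normal-N libraries and at 10 FPKM or more in all 6 low-N libraries, and 0 did the reverse. Of these 38, 60.5% have an ID that does not end in 00, against 7.63% of the tested genes. Potri.007G062282 and Potri.007G062061, the IDs with the largest low-N rise in both genotypes by the naming rule, are among the 38. The effect of N supply on the plants stays open as the biological explanation and was not tested apart from batch.

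For the rise of Potri.014G103000 in wild type at low N, reads of the overexpression low-N libraries would need a share of 2.27%, by the group means. Of the 1095 genes with a mean of at least 100 FPKM in overexpression roots at low N, 0 lay below that share in every wild-type low-N library, although the mean of Potri.016G057600 did, at 1.68%. In wild-type low-N replicate 1 Potri.016G057600 lay below Potri.014G103000, at 29.4 and 55.4 FPKM, although it was higher in each overexpression low-N library. In replicates 2 and 3 it was the higher one, at 81.0 against 51.0 and 30.2 against 28.2 FPKM. This order rests on 1 ID in 1 library and does not decide the question. Reads of the normal-N overexpression libraries were not examined. Mixed reads therefore cannot be told apart from a response of the gene to low N. Too few genes are specific enough to overexpression roots to decide. The response to N supply itself stays open and was not tested further.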

How the results depend on the processing

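The fits without the Potri.013G run, the settings of the interactions of named IDs, the settings of its shift and the correlation of the low-N genotype effect with the wild-type low-N response were chosen after seeing the data. A fold threshold of 1 on the log2 scale lowered the calls to 535 and 1936 for the genotype effect at normal and low N, to 4154 and 3929 for the low-N response in wild type and overexpression roots, and to 2429 for the interaction, by its construction. Library weights raised the calls for the genotype effect at normal N from 5851 to 11246, and the cause was not tested. At low N the weights gave 10669 calls, so the N supply with more genotype calls turned over. Fits on the 2 groups alone gave 8535 calls at normal N and 9608 at low N. Leaving out 1 library gave 3706 to 4947 calls for the genotype effect at normal N, the lowest without overexpression normal-N replicate 3, and fewer samples were fitted. All other settings set in advance left the counts within 1.5 times, and leaving out the Potri.013G run gave 5796, 11673, 16796, 17006 and 8787 calls in the 5 contrasts. With the replicate number as a replicate block, the counts were 5424, 11541, 16758, 16957 and 8453, with no count moved by over 1.5 times and no named ID moved across the threshold. Deviations of same-numbered libraries from their group means correlated at -0.127 to 0.0942 over 18 pairs, and 4 of the 12 libraries correlated best with their own number in another group, so the numbers were not treated as pairs. The correlation of the low-N responses moved from 0.68 to 0.708 with a pseudocount of 0.1. The correlation of the normal-N genotype effect with the wild-type low-N response moved from 0.154 to 0.129 with a filter at 5 FPKM, to 0.123 after median-of-ratios scaling and to 0.189 after quantile normalization, and the cause was not tested. The log2 fold changes of the named IDs kept their sign and side of the threshold in 178 alternatives, the 2 exceptions being those of Potri.014G103000 given with the low-N response of overexpression roots. Their interactions kept their side of the threshold in 205 alternatives, with 3 exceptions, all of Potri.007G062282. The shift of the Potri.013G run ranged from 0.456 to 0.476 at normal N and from 0.128 to 0.472 at low N when 1 library was left out, the lowest without wild-type low-N replicate 2. Gene list tests were not run, since the IDs carry no names. Depth was inferred from low FPKM values and only relative between libraries, which limits what can be said of genes below about 1 FPKM at low N.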

Other observations

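The test of which ID is the overexpressed gene and the comparison by ID ending were chosen only after the result was seen. Potri IDs that do not end in 00 had a higher share of rises at low N than the rest, a difference for which no test was run. In wild type, 22.1% of these 1875 tested IDs rose by at least 1 on the log2 scale and 6.83% fell by that much, against 9.38% and 6.54% of the IDs that end in 00. In overexpression roots the shares were 23.9% and 5.44%, against 10.3% and 4.55%.

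The most abundant genes took different shares of the libraries. The 10 genes with the highest FPKM held 5.08% to 5.38% of the FPKM sum in wild type at low N, 6.67% to 7.22% in wild type at normal N, 8.42% to 8.62% in overexpression roots at normal N and 7.69% to 8.35% in overexpression roots at low N.

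Potri.014G103000 may be the row of the overexpressed gene, which the table does not name. It was the 1 ID raised by at least 2 on the log2 scale at both N supplies, with the next at 1.95, but it was picked for this effect and the limit of 2 was set afterwards. The count therefore does not decide whether it is the overexpressed gene, and a gene that follows the overexpressed one could look the same.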
